A study of Mus musculus with 24 samples.

How the data were processed

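Liver and left ventricle RNA was sequenced from mice of 4 genotypes that combine 2 nuclear genomes, C57BL/6 (written BL/6J) and NZB, with the mitochondrial DNA (mtDNA) of C57 or NZB mice. Each genotype is written as nuclear genome, colon, mtDNA. BL/6J:C57 and NZB:NZB are the parental combinations, and BL/6J:NZB and NZB:C57 are the conplastic lines, in which 10 generations of backcrossing placed a nuclear genome on the mtDNA of the other strain. Per the labels' protocols, polyadenylated RNA came from 12 males per genotype aged 10 weeks, RNA integrity was at least 7.9, and equal parts of RNA from 4 animals were pooled, giving 3 pools per genotype and tissue. Within a tissue the replicates are therefore pools of different animals, and a p-value measures the spread between pools. Liver and heart pools of a genotype may hold the same animals, while the fit over both tissues took them as independent. The titles of BL/6J libraries carry the word mix and those of NZB libraries the word rep, so any difference in handling that follows this word cannot be told apart from the nuclear genome.

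The deposited table holds 15323 Ensembl genes and 24 library columns, each matched to its sample by name, with 0 columns left unmatched. The submitters' processing notes name cutadapt 1.2.1, RSEM 1.2.3, Bowtie2 2.0.6, edgeR without a version, and the genome build GRCm38, with no role or order. The values are a signal normalised by the authors, as the word in the deposited column names says. In every column, 100% of the values were whole multiples of 1 constant within 0.01 reads, so whole reads per gene were recovered by dividing by that constant. The recovered totals ran from 7294525 to 34974268 reads in liver and from 3714278 to 12949956 in heart. Genes absent from the table may have been removed by the authors, and the rule for that is not given in the sources used here. Symbols and positions came from the GENCODE vM21 annotation of GRCm38, which gave a symbol to 15106 genes (98.58%) and a position to 15116. The 13 mRNAs encoded by mtDNA were not analysed here. For 55 genes the values equalled those of another gene in all libraries.

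The tests were planned for counts with edgeR's quasi-likelihood test, with limma as the stated choice if the values were normalised. Since they were, limma 3.58.1 (trend) in R 4.3.3 was fitted to log2(value + 1), so a log2 fold change understates the change of low genes. Genes with a value of at least 1 in at least 3 libraries of a fit were tested: 13159 in liver, 13803 in heart and 14968 over both tissues. The 12 libraries of a tissue shared 1 fit, and the 24 libraries shared 1 fit for differences between tissues. Per tissue, each conplastic line was compared with the parental line of its nuclear genome, followed by the mean of these effects (mismatch), the mean difference between NZB and C57 mtDNA, and the mean difference between NZB and BL/6J nuclear genomes. Adjusted p-values are by Benjamini-Hochberg over all genes tested, with a threshold of 0.05, from limma unless another tool is named. Values are normalised read counts, given as mean ± SD over 3 pools.

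Before the data were examined, 47 gene lists (pathways, protein complexes, cell type markers and 4 single genes) with 1120 names were written from textbook knowledge, of which 1033 names were in the table. Lists with at least 5 tested members were tested with limma's camera at a correlation of 0.01, adjusted over the lists of 1 comparison, and again with a correlation estimated from the data and with fry. Counts of members are given over all genes tested and adjusted over the list alone. Genes named in the text follow a rule written at the same time. For a conplastic line against its parental line these are the 8 highest and 8 lowest fold changes among called genes with no overlap between libraries, leaving out predicted gene models, and up to 4 called members of each list by smallest p. The averaged comparisons take 5 highest, 5 lowest and up to 2 per list, the tissue differences take the 5 smallest p, and Nnt, Mmrn1 and Cox7a2l are given in any case. Some genes that meet the rule are not reported here. Genes outside the rule are said to be chosen after their values were seen.

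Sequence sharing was measured as the share of a gene's words of 31 bases that also occur in another annotated gene's transcripts. Of 15106 genes, 2159 shared at least 10%, and reads of such genes may be divided among copies. Beside the genes for which the results say so, this holds for Akap2, Cdc20, Ces2a, Cox7c, Ifit1, Mrpl27, Ndufs6, Nnt, Rnf125 and Slc22a26, whose own levels are uncertain. Because antisense transcripts and overlapping genes cannot be separated without strand information, which is not given in the sources used here, their values are uncertain. The tests were tested on simulated counts drawn from the real means, with known changes. The changed genes were taken only from those above a minimum mean level, so recovery of low genes is not shown. For BL/6J:NZB against BL/6J:C57 in liver, 28 of 67 genes changed 1.5-fold, 57 of 67 changed 2-fold and 66 of 66 changed 4-fold were recovered among 13159 genes, and in heart 44, 64 and 66 among 13803 genes. For NZB:C57 against NZB:NZB the numbers were 31, 62 and 65 in liver and 42, 64 and 66 in heart. For the tissue differences they were 12, 40 and 64 on the BL/6J nuclear genome and 15, 48 and 63 on the NZB nuclear genome.

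Alternatives chosen beforehand were DESeq2 1.42.0 on recovered reads, RLE size factors, library totals without scaling factors, no filter on low values, pseudocounts of 0.5 and 2, the replicate number as a block, only the 6 libraries compared, and leaving out each library in turn. After seeing the data, edgeR 4.0.16 on recovered reads, TMM factors recomputed within a fit, only genes with reads in every NZB-nuclear library, and a fit without genes sharing sequence were added. Figures and pattern tests used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.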

Results

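The series compared the transcriptomes of conplastic and parental mice in liver and heart, to ask what a mismatch between mtDNA and nuclear genome changes. There were 4 genotypes in 2 tissues, with 3 libraries in each group and 24 in all. Recovered reads ran from 7294525 to 34974268 per liver library and from 3714278 to 12949956 per heart library. The 20 genes with the most reads took 33.4% to 34.1% of the reads in NZB:C57 hearts, against 11.5% to 14.5% in the other hearts and 24.4% to 30.3% in livers. NZB:C57 hearts also had larger sums of values over all genes, from 1048700 to 1068800, than the other hearts, from 643486 to 726047.

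In livers with the BL/6J nuclear genome, NZB mtDNA in place of C57 mtDNA changed 1 gene. Gm13340 (chromosome 2, 22588103 to 22589647), annotated as an unprocessed pseudogene and chosen for the text after its values were seen, rose from 0.564 ± 0.147 to 14.3 ± 9.44 (log2 fold change 3.13, SE 0.34, adjusted p = 0.00433, limma). It shares 45.2% of its 31-base words with mt-Co1, the mtDNA gene for a catalytic subunit of cytochrome c oxidase, so its reads cannot be assigned with certainty. Its levels in every library are shown in the plot of 3 genes by library.

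No list member passed the threshold over all genes in these livers, and of 40 lists tested 15 passed it with camera and 0 with an estimated correlation. Of 37 acute phase and complement genes, which encode plasma proteins of the inflammatory response, 14 were lower when adjusted over the list alone, with a median log2 fold change of -0.38 (camera adjusted p = 2.74e-11, but adjusted p = 0.374 with an estimated correlation). Members chosen after their values were seen include Saa3 at 41.5 ± 41.0 in BL/6J:C57 and 5.002 ± 1.255 in BL/6J:NZB, Hp at 8670 ± 3358 and 3793 ± 530.4, and Lcn2 at 465 ± 637 and 19.3 ± 20.3. Markers of stellate cells and fibroblasts had a median of 0.43, with 8 of 17 higher adjusted over the list alone (camera adjusted p = 3.83e-11, adjusted p = 0.369 with an estimated correlation). Among them, Reln was 19.3 ± 2.39 and 40.3 ± 7.11, and Hgf was 1.17 ± 0.327 and 4.85 ± 1.81, both chosen after their values were seen. Endothelial markers had a median of 0.39 with 6 of 20 higher adjusted over the list alone, and extracellular matrix genes a median of 0.33 with 7 of 30 (camera adjusted p = 5.07e-10 and 3.14e-09, adjusted p = 0.374 for both with an estimated correlation). Hepatocyte markers had a median of -0.20 and macrophage and Kupffer cell markers one of 0.18. Of 19 members of each, 0 passed the threshold over all genes or adjusted over the list alone. The camera adjusted p-values were 0.00233 and 0.00568, and adjusted p = 0.369 and 0.698 with an estimated correlation. With fry, hepatocyte markers were the 1 list to pass in these livers (adjusted p = 0.0360). The 77 mitochondrial ribosomal protein genes had a median of -0.17 and the 36 nuclear genes of respiratory complex I a median of -0.18, with 0 members past the threshold either way (adjusted p = 0.428 and 0.687 with an estimated correlation). At an unadjusted p under 0.05 there were 1284 genes, while edgeR called 3 and DESeq2 84. Without BL/6J:C57 replicate 3 limma called 195 genes, without replicate 1 it called 2, and without BL/6J:NZB replicate 1 or 3 it called 3, while the fit to only the 6 libraries compared and the fit without a filter on low values called 0.

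In hearts with the BL/6J nuclear genome, NZB mtDNA raised 59 genes and lowered 70 of 13803 tested. Myh7 (chromosome 14, 54970684 to 54994626), the beta-myosin heavy chain, rose from 82.9 ± 12.8 to 157 ± 25.6 (log2 fold change 0.91, SE 0.11, adjusted p = 0.00192, limma). It shares 31.9% of its words with other genes, foremost Myh6, which was 14049 ± 928 in BL/6J:C57, so its own level is uncertain. Malat1 (chromosome 19, 5795690 to 5802672), a nuclear long noncoding RNA, rose from 561 ± 62.7 to 1014 ± 93.3 (0.86, SE 0.11, adjusted p = 0.00192). The sodium-calcium exchanger Slc8a1 (chromosome 17, 81373105 to 81738377) fell from 115 ± 14.6 to 59.8 ± 10.496 (-0.94, SE 0.13, adjusted p = 0.00667). Gm13340, chosen after its values were seen, rose from 1.33 ± 0.209 to 92.2 ± 23.2 (5.29, SE 0.17, adjusted p = 2.78e-12). The myosin gene Myh7b rose by a log2 of 0.78, the heparan sulfate proteoglycan Gpc3 by 0.88 and the membrane glycoprotein Gpm6a by 0.81.

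Some nuclear genes of the respiratory chain rose in these hearts. In complex I, 2 of 36 members rose over all genes and 14 adjusted over the list alone, with a median of 0.19. Ndufa5 rose from 249.9 ± 21.5 to 344 ± 39.8 and Ndufs6 from 189 ± 9.65 to 248 ± 28.4. In complex IV, 2 of 14 rose over all genes and 10 adjusted over the list alone, with a median of 0.25. Cox7b went from 474 ± 25.1 to 631 ± 66.0 and Cox7c from 201 ± 14.6 to 310.2 ± 63.6. Among 15 nuclear ATP synthase genes 2 rose, 7 adjusted over the list alone, including Atp5l (log2 0.46) and the inhibitory factor Atpif1 (0.40). The camera adjusted p-values were 4.13e-10, 3.38e-08 and 2.5e-05, and adjusted p = 0.600 for each with an estimated correlation. Of 13 complex II and III genes 0 passed over all genes and 3 were higher adjusted over the list alone, with a median of 0.05 (camera adjusted p = 0.0633, adjusted p = 0.6397 with an estimated correlation). Of 77 mitochondrial ribosomal protein genes 1 rose, Mrpl27 (0.44), and 1 did so adjusted over the list alone. Slirp, which stabilises mitochondrial mRNAs, rose by 0.51.

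Interferon-stimulated genes had a median of 0.22, with 3 of 37 up over all genes and 9 adjusted over the list alone (camera adjusted p = 3.55e-09, adjusted p = 0.269 with an estimated correlation). Ifit1 rose from 6.78 ± 0.0929 to 11.8 ± 0.404 and the guanylate-binding protein gene Gbp3 from 14.8 ± 2.38 to 23.3 ± 1.65. The antigen peptide transporter gene Tap1 rose by 0.55. Cardiac ion channel and calcium handling genes had a median of -0.20 (camera adjusted p = 1.87e-07, adjusted p = 0.269 with an estimated correlation). This list was the 1 list to pass with fry in these hearts (adjusted p = 0.0498). Of its 28 members 4 fell over all genes and 12 adjusted over the list alone. Besides Slc8a1, these included the calcium release channel Ryr2 (1364 ± 88.0 to 929.9 ± 60.0) and Jph2, which tethers the sarcoplasmic reticulum (389 ± 42.8 to 301 ± 16.0). The triglyceride synthesis genes Gpam and Lpin1 fell by 0.65 and 0.48 on the log2 scale, Dag1 (dystroglycan) by 0.61, Acta2 by 0.55, Col15a1 by 0.53, Xirp1 by 0.51 and the complement gene C7 by 0.77. Adjusted p-values of these genes lay between 0.0214 and 0.0473. Hepatocyte markers, which a heart should hold only in traces, had a median of 0.95, with 0 of 17 past the threshold over all genes and 6 adjusted over the list alone (adjusted p = 0.600 with an estimated correlation). The count of 129 fell to 8 without BL/6J:C57 replicate 1, 6 without its replicate 3, 8 without BL/6J:NZB replicate 2 and 6 without its replicate 3. It was 1 in a fit to only the 6 libraries compared, 3 without a filter on low values, 322 with edgeR and 423 with DESeq2, and library totals gave 100 higher and 54 lower.

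**Figure D1:**
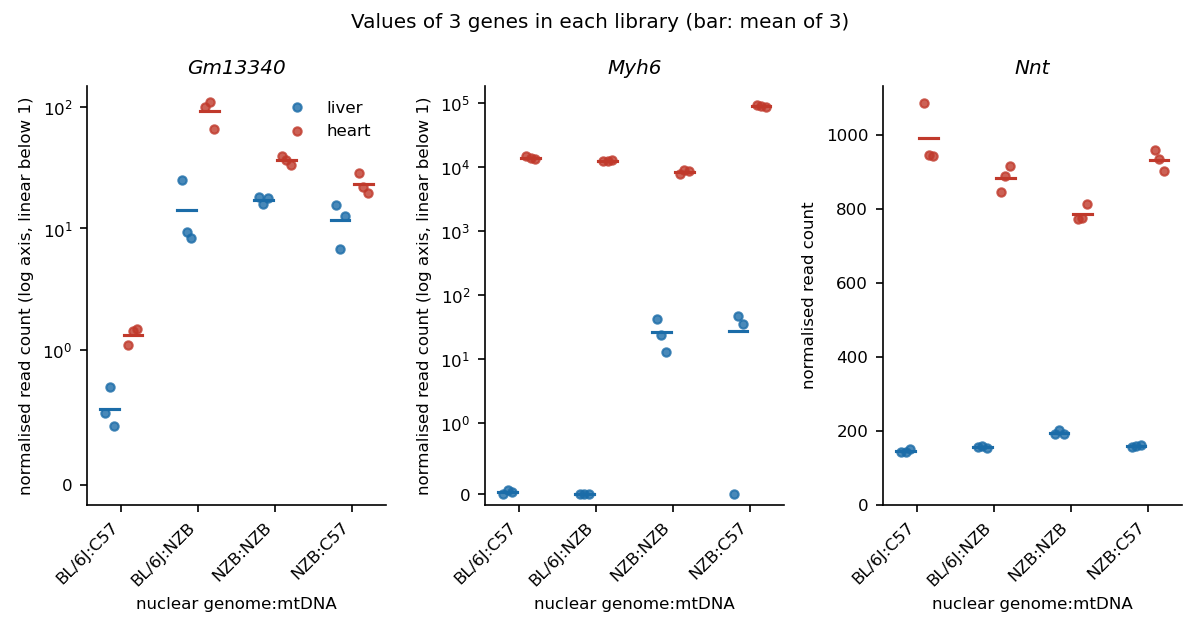
Normalised read counts of Gm13340, Myh6 and Nnt in each of the 24 libraries, by genotype (nuclear genome:mtDNA), with points for libraries and bars for the mean of 3. The axes of Gm13340 and Myh6 are logarithmic above 1 and linear below, and that of Nnt is linear. Gm13340 is lowest in BL/6J:C57 (0.564 in liver, 1.33 in heart) and Myh6 is highest in NZB:C57 hearts (89529).

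In livers with the NZB nuclear genome, 480 genes were higher and 584 lower in NZB:C57 than in NZB:NZB, of 13159 tested. Over the 7550 genes above 5 in every library, liver changes opposed those of heart (Pearson's r of -0.87, 81.0% of genes of opposite sign). Genes near 0 in heart, such as Baat, lie outside that set. Whether read counts were adjusted across both tissues before deposit stays open, so the changes are not attributed to C57 mtDNA here. The genes furthest apart were known for different expression in livers of males and females, although all mice were labelled male. Ddx3y, a gene of the Y chromosome, had between 364 and 2245 reads in every liver library, and Kdm5d between 117 and 731. Which NZB-nuclear library came from which mtDNA was not checked here beyond the labels in either tissue. The direction of this comparison rests on them, and wrong labels are not excluded. Mup17 (chromosome 4, 61591929 to 61595871), which encodes a major urinary protein, rose from 9.02 ± 5.77 in NZB:NZB to 703 ± 205 in NZB:C57 (log2 fold change 6.24, SE 0.42, adjusted p = 2.28e-07, limma). Of 21 female-biased liver genes 20 fell over all genes and 21 adjusted over the list alone, with a median of -2.94 (camera adjusted p = 5.75e-33, adjusted p = 0.00203 with an estimated correlation). Of 24 male-biased liver genes 18 rose and 19 adjusted over the list alone, with a median of 1.71 (6.49e-32, adjusted p = 0.0400 with an estimated correlation).

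Among the female-biased genes, the cytochrome P450 gene Cyp3a41b fell from 40.1 ± 13.4 to 0.146 ± 0.0601, Cyp2b9 from 99.1 ± 25.3 to 4.27 ± 4.30 and Cyp2c40 from 796 ± 55.8 to 67.7 ± 48.5. Hao2, a peroxisomal hydroxyacid oxidase, fell from 49.9 ± 7.94 to 3.12 ± 5.10, A1bg from 72.4 ± 47.7 to 2.22 ± 1.96, and the transporter Slc22a26 from 68.5 ± 17.4 to 7.91 ± 2.51. Cyp2b13 was 12.6 ± 4.47 in NZB:NZB and had 0 reads in all 3 NZB:C57 livers. Among the male-biased genes, Mup7 rose from 128 ± 40.7 to 2276 ± 494, Mup18 from 0.576 ± 0.590 to 96.6 ± 15.7 and Mup20 from 36.5 ± 9.12 to 535 ± 52.6. Mup genes are near-identical copies of each other, so how reads were divided among them is uncertain. The Cyp genes named here also share sequence with other Cyp genes.

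Some genes of hepatocyte function also rose. Of 21 bile acid genes 11 rose and 1 fell, 12 and 1 adjusted over the list alone, with a median of 0.52 (adjusted p = 0.0776 with an estimated correlation). Baat, which conjugates bile acids, rose from 171 ± 1.68 to 837 ± 21.97, the canalicular exporter Abcc2 from 363 ± 55.2 to 1364 ± 44.9 and the bile acid importer Slc10a1 from 542 ± 41.3 to 1914 ± 244. Ugt1a1, the bilirubin-conjugating enzyme, which shares sequence with Ugt1a5, rose by 3.87 (SE 0.12, adjusted p = 4.14e-10) and the carboxylesterase Ces2a by 1.84. The terminal complement genes C6 and C9 rose by 2.31 and 2.38, and 8 of 37 acute phase and complement genes rose and 1 fell, 10 and 2 adjusted over the list alone (adjusted p = 0.840 with an estimated correlation). Hepatocyte markers had 8 of 19 up and 1 down, 9 and 1 adjusted over the list alone (adjusted p = 0.0400 with an estimated correlation), such as Apoh (0.47) and Rbp4 (0.57).

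Many endothelial and stellate cell markers fell in the same comparison. Of 20 endothelial markers 11 fell, 17 adjusted over the list alone, with a median of -0.97 (adjusted p = 0.166 with an estimated correlation), including Kdr (65.3 ± 5.99 to 24.4 ± 2.87) and Cdh5 (36.6 ± 3.82 to 14.5 ± 1.78). Stellate cell and fibroblast markers had 10 of 17 down, 16 adjusted over the list alone, with Reln falling from 72.5 ± 4.70 to 24.2 ± 6.98. Of 30 extracellular matrix genes 15 fell and 1 rose, 22 and 1 adjusted over the list alone, with Sparc falling by 1.32. Of 35 cell cycle genes 16 fell, 27 adjusted over the list alone, with Mki67 falling by 1.46. Each of these 3 lists had adjusted p = 0.142 with an estimated correlation. Macrophage and Kupffer cell markers had 5 of 19 down and 1 up, 15 and 1 adjusted over the list alone (adjusted p = 0.484 with an estimated correlation), with Mrc1 falling from 59.2 ± 10.0 to 28.1 ± 8.70 and Cd5l rising from 69.9 ± 12.7 to 162 ± 35.4. Of 4 T and NK cell markers 1 rose, 1 adjusted over the list alone (Cd3e, 0.901 ± 0.0876 to 4.53 ± 1.07). Of 4 B and plasma cell markers 2 rose, 2 adjusted over the list alone (Igkc, 6.75 ± 0.489 to 13.9 ± 2.85, and Jchain, 4.996 ± 0.710 to 9.63 ± 1.64), and both lists were too short for the list test. Jchain missed the threshold without NZB:NZB replicate 3 (0.72) or NZB:C57 replicate 2 (0.76). The count of 1064 was 681 without NZB:NZB replicate 1 and 703 without its replicate 2, and 598 (175 higher, 423 lower) over genes with reads in every NZB-nuclear library. Library totals without scaling factors shifted the median of all genes to -0.22 and gave 355 higher and 2562 lower.

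The change in these livers went with reads in hearts of the same genotypes. Genes whose number of heart libraries at 0 reads was the same in NZB:C57 and NZB:NZB had a median liver change of 0.01 (6151 genes). With 1, 2 or 3 more NZB:C57 hearts at 0 reads, the medians were 1.29 (128 genes), 2.24 (34 genes) and 2.95 (5 genes), and with 1 more NZB:NZB heart at 0 reads it was -0.61 (49 genes). Ugt1a1 had 0 reads in 3 NZB:C57 hearts, and Baat and Abcc2 had 0 reads in 2, while each was read in all 3 NZB:NZB hearts.

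In hearts with the NZB nuclear genome, 1791 genes were higher and 399 lower in NZB:C57 than in NZB:NZB, of 13803 tested, and transcripts of heart muscle stood highest. Over the 7550 genes above 5 in every library, heart changes opposed those of liver (Pearson's r of -0.87, 81.0% of genes of opposite sign). Genes near 0 in livers, such as Myh6 and Trim63, lie outside that set. An adjustment of read counts across both tissues stays open, so the heart changes are not attributed to C57 mtDNA here. As in liver, the direction rests on the labels. Myh6 (chromosome 14, 54941921 to 54966927), the alpha-myosin heavy chain, rose from 8397 ± 621 in NZB:NZB to 89529 ± 2366 in NZB:C57 (log2 fold change 3.42, SE 0.11, adjusted p = 1.12e-13, limma). Myh6 shares 32.5% of its words with other genes, foremost Myh7, so how reads were divided between both is uncertain. Mb (chromosome 15, 77015487 to 77050670), myoglobin, rose from 4823 ± 437 to 57191 ± 668 (3.57, SE 0.10, adjusted p = 1.76e-14). Of 24 sarcomere genes 21 rose, 22 adjusted over the list alone, with a median of 1.89 (camera adjusted p = 6.64e-32, adjusted p = 0.00210 with an estimated correlation). Of 13 cardiomyocyte markers 12 rose, 12 adjusted over the list alone, with a median of 2.72 (adjusted p = 0.00210 with an estimated correlation). Of 28 ion channel and calcium handling genes 23 rose, 23 adjusted over the list alone, with a median of 1.47 (adjusted p = 0.00424 with an estimated correlation).

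In the sarcomere, cardiac actin Actc1 rose from 5003 ± 596 to 43692 ± 1559.8, the light chain Myl3 from 2217 ± 127 to 17441 ± 633, alpha-actinin Actn2 from 858 ± 31.02 to 6097 ± 142 and Ldb3 from 499 ± 12.9 to 2719.7 ± 70.8. Myoz2 and the muscle creatine kinase Ckm rose by 2.72 and 2.89. Among channel and calcium genes, the potassium channel Kcnj3 rose from 19.6 ± 3.98 to 314 ± 15.6, and Jph2, Trdn and Cacna2d1 by 2.30, 2.71 and 2.60. The muscle ubiquitin ligase Trim63 (chromosome 4, 134315120 to 134329629) rose from 93.4 ± 5.82 to 1221 ± 80.2 (3.69, SE 0.07, adjusted p = 4.07e-16), and Trim54 from 59.3 ± 5.07 to 793 ± 61.6. Of 12 atrial markers 10 rose and 1 fell, 10 and 1 adjusted over the list alone (adjusted p = 0.0899 with an estimated correlation), among them Nppa (382 ± 51.7 to 4688 ± 1741), Myl7 (98.8 ± 38.5 to 905 ± 246) and Bmp10 (5.95 ± 1.58 to 91.6 ± 17.1). Edn3, an endothelin, rose from 1.64 ± 0.577 to 32.5 ± 11.5.

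Among other groups in these hearts, endothelial markers had 12 of 17 up, 13 adjusted over the list alone (adjusted p = 0.0899 with an estimated correlation), with Kdr rising from 219 ± 5.01 to 409 ± 34.5, and a median of 0.66 that library totals turned to -0.04. Stellate cell and fibroblast markers had 13 of 17 up, 13 adjusted over the list alone (adjusted p = 0.0314 with an estimated correlation), with Dcn rising by 0.81, and a median of 0.55 that library totals turned to -0.04. Of 35 PPARA targets and fatty acid oxidation genes 13 rose, 18 adjusted over the list alone, with Cd36 up by 1.25 and a median of 0.17 that library totals turned to -0.51 (adjusted p = 0.587 with an estimated correlation). The muscle isoforms of complex IV subunits, Cox8b and Cox6a2, rose by 2.13 and 1.48. Of 20 ER chaperone genes 9 fell, 11 adjusted over the list alone (adjusted p = 0.582 with an estimated correlation), with Pdia4, Pdia6 and Calr falling by 0.53, 0.47 and 0.33. Female-biased liver genes, here at low levels, had 8 of 9 up, 8 adjusted over the list alone (adjusted p = 0.00809 with an estimated correlation), including Cux2 (6.24 ± 0.320 to 47.9 ± 8.52). Mup7 went from 32.4 ± 30.0 to 0.665 ± 0.242 (adjusted p = 0.0383), Scara5 from 48.0 ± 1.75 to 14.3 ± 2.12 and Ccdc69 from 13.1 ± 2.01 to 2.80 ± 0.530.

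The change in these hearts went with reads in livers of the same genotypes. Genes whose number of liver libraries at 0 reads was the same in NZB:C57 and NZB:NZB had a median heart change of -0.01 (5866 genes). With 1, 2 or 3 more NZB:C57 livers at 0 reads, the medians were 1.56 (155 genes), 2.14 (89 genes) and 3.01 (27 genes). On the BL/6J nuclear genome the medians at 0 and 1 were -0.03 (5847 genes) and -0.05 (45 genes). Trim63 had 0 reads in all 3 NZB:C57 livers and 3, 4 and 1 in NZB:NZB livers, while Atp2a2, chosen after its values were seen and read in all livers, was between 9780 and 10618 in NZB:NZB hearts and between 12797 and 13311 in NZB:C57 hearts. Over genes with reads in every NZB-nuclear library the count of 2190 was 1054 (786 higher, 268 lower). Library totals moved the median of all genes to -0.65 and gave 803 higher and 10233 lower.

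**Figure D2:**
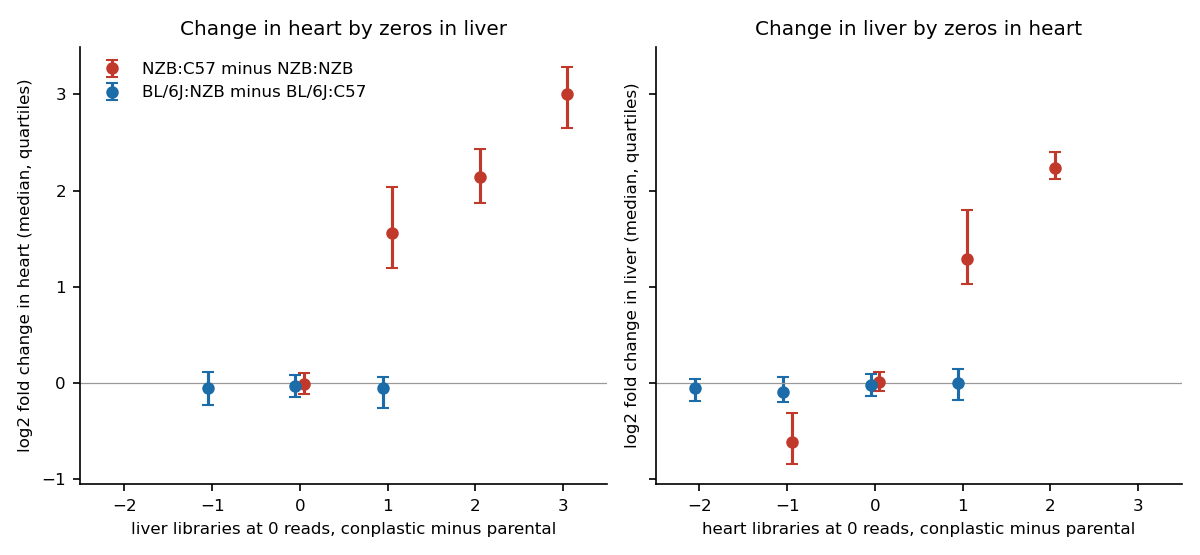
Median log2 fold change (points, with quartiles as bars) of the conplastic against the parental line in heart (left) and liver (right), by how many more libraries of the conplastic line held 0 reads of the gene in the other tissue, for each nuclear genome and classes of at least 20 genes. On the NZB nuclear genome the median goes from -0.01 at 0 to 1.56, 2.14 and 3.01 at 1, 2 and 3 in heart and from 0.01 at 0 to 1.29 and 2.24 at 1 and 2 in liver, while on the BL/6J nuclear genome it is -0.03 and -0.05 at 0 and 1 in heart and -0.02 and -0.0042 in liver.

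Averaged over both nuclear genomes, 240 liver genes were higher and 88 lower in the conplastic than in the parental lines (mismatch). Among 100 splits of these libraries 7, the real one included, called as many genes, so chance could not be excluded for this count. Ido2, an enzyme of tryptophan breakdown, had a mean change of 1.35 (SE 0.06, adjusted p = 2.36e-08, limma), with 93.3 ± 4.08 in BL/6J:C57, 105 ± 6.48 in BL/6J:NZB, 77.9 ± 5.99 in NZB:NZB and 458 ± 19.5 in NZB:C57. Akr1d1, a bile acid synthesis enzyme, was 133 ± 7.76, 159 ± 11.7, 198 ± 4.27 and 874 ± 120.4 in the same order, Cpb2 was 402 ± 56.8, 314 ± 24.04, 295 ± 14.7 and 1775 ± 248, and the glutamate transporter Slc17a8 was 8.80 ± 1.16, 16.4 ± 3.41, 14.3 ± 1.86 and 68.8 ± 19.1. Rnf125 rose by a mean of 1.08 on this scale, and Pla2g12b, Ckap2l, Snhg11, Fendrr and Myom3 fell by 0.71, 0.69, 0.68, 0.70 and 0.74. Female-biased genes had 15 of 21 down, 20 adjusted over the list alone, and male-biased genes 15 of 24 up, 19 adjusted over the list alone (adjusted p = 0.00149 and 0.0488 with an estimated correlation). On the BL/6J nuclear genome alone 0 members of either list passed either way. Their medians there were 0.0019 (11 of 21 above 0) and -0.15 (6 of 24 above 0), so these list changes come from the NZB nuclear genome. Bile acid genes had 7 of 21 up, 12 up and 1 down adjusted over the list alone, and cell cycle genes 2 of 35 down, 17 adjusted over the list alone (adjusted p = 0.0775 and 0.199 with an estimated correlation). For these lists too, 0 members passed either way on BL/6J alone, with medians of -0.05 and 0.0057. Over genes with reads in every NZB-nuclear library the count of 328 was 46 (23 higher, 23 lower), and library totals gave 203 higher and 170 lower.

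Averaged over both nuclear genomes, 1354 heart genes were higher and 196 lower in the conplastic than in the parental lines. The split of the same hearts by mtDNA called more genes (1945), so the count does not single out mismatch. Mb was 6252 ± 62.5 in BL/6J:C57 and 6949 ± 197 in BL/6J:NZB beside 4823 ± 437 in NZB:NZB and 57191 ± 668 in NZB:C57, a mean change of 1.86 (SE 0.07, adjusted p = 4.17e-12, limma). Myh7 was 82.9 ± 12.8, 157 ± 25.6, 707 ± 47.0 and 4883 ± 432 in that order, and Zfpm2, a cofactor of GATA factors, was 10.2 ± 1.54, 7.60 ± 0.533, 7.94 ± 1.12 and 86.1 ± 6.07. Edn3 and Myh6 rose by means of 2.13 and 1.62, although Myh6 was 14049 ± 928 in BL/6J:C57 and 12500.3 ± 253 in BL/6J:NZB. Ccdc69 fell by 1.04, Inka2 by 0.76, Col15a1 by 0.76, Aoc3 by 0.65 and Moxd1 by 0.67. Sarcomere genes had 21 of 24 up and 1 down, 22 and 1 adjusted over the list alone (adjusted p = 0.00150 with an estimated correlation). On the BL/6J nuclear genome alone 1 rose and 1 fell over all genes, with a median of 0.05, so this list change comes mainly from the NZB nuclear genome. Complex IV genes had 5 of 14 up, 7 adjusted over the list alone, and complex I genes 1 of 36, 1 adjusted over the list alone (adjusted p = 0.618 and 0.824 with an estimated correlation), and library totals turned their medians from 0.15 to -0.18 and from 0.08 to -0.25. The count of 1550 was 592 over genes with reads in every NZB-nuclear library, and library totals gave 685 higher and 8442 lower with a median of -0.30.

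With NZB against C57 mtDNA, averaged over both nuclear genomes, 471 liver genes were higher and 405 lower. This average includes the NZB-nuclear changes, which opposed those of heart over the 7550 genes above 5 in every library. Reln, an extracellular glycoprotein made by stellate cells, was 19.3 ± 2.39 in BL/6J:C57, 40.3 ± 7.11 in BL/6J:NZB, 72.5 ± 4.70 in NZB:NZB and 24.2 ± 6.98 in NZB:C57, a mean change of 1.30 (SE 0.13, adjusted p = 2.55e-05, limma). Plxnc1, Ccdc80, Akap2 and C1qtnf1 rose by 1.17, 1.14, 1.13 and 1.11. The acute phase gene Saa3 fell by 2.37 (adjusted p = 0.00210), Orm2 by 3.23 and Orm3 by 1.96, with wide spread among C57 mtDNA livers, such as 318 ± 327 for Orm2 in BL/6J:C57 and 187 ± 269.6 in NZB:C57. Orm2 shares sequence with Orm1. Wfdc21 fell by 1.51 and Cpb2 by 1.46. Stellate cell and fibroblast markers had 12 of 17 up and endothelial markers 11 of 20, both 16 adjusted over the list alone (adjusted p = 0.147 and 0.158 with an estimated correlation). Acute phase and complement genes had 12 of 37 down, 20 down and 3 up adjusted over the list alone (adjusted p = 0.481 with an estimated correlation), and hepatocyte markers 8 of 19 down, 10 down and 1 up adjusted over the list alone (adjusted p = 0.0460 with an estimated correlation). The count of 876 was 1370 without BL/6J:C57 replicate 3 and 541 over genes with reads in every NZB-nuclear library, and library totals gave 2683 higher and 280 lower with a median of 0.14.

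In heart, 401 genes were higher and 1544 lower with NZB mtDNA on average over both nuclear genomes. This average includes the NZB-nuclear changes, which opposed those of liver over the 7550 genes above 5 in every library. Alpk2, a cardiac kinase, was 124 ± 11.2 in BL/6J:C57, 89.0 ± 9.15 in BL/6J:NZB, 97.5 ± 10.3 in NZB:NZB and 788 ± 24.4 in NZB:C57, a mean change of -1.74 (SE 0.06, adjusted p = 3.49e-12, limma). Zfpm2, Myh6, Mb and Actc1 fell by means of 1.83, 1.79, 1.71 and 1.69, although Mb was higher in BL/6J:NZB than in BL/6J:C57 hearts, as given for mismatch. Myh7b was higher with NZB mtDNA on both nuclear genomes, at 59.2 ± 12.3 and 101 ± 7.11 on BL/6J and 62.7 ± 6.02 and 102 ± 3.97 on NZB (0.74, SE 0.08, adjusted p = 4.47e-06). Slitrk6, Ccdc69, Moxd1 and Slc26a3 rose by means of 0.90, 0.85, 0.85 and 0.79, although Ccdc69 was lower in BL/6J:NZB (15.9 ± 0.973) than in BL/6J:C57 hearts (18.2 ± 0.872). Interferon-stimulated genes had 6 of 37 up, 10 adjusted over the list alone, and ER chaperones 8 of 20, 13 adjusted over the list alone (adjusted p = 0.245 and 0.376 with an estimated correlation). Complex I genes had 4 of 36 up, 2 adjusted over the list alone (adjusted p = 0.563 with an estimated correlation). The count of 1945 was 1033 over genes with reads in every NZB-nuclear library, and library totals gave 9230 higher and 640 lower with a median of 0.33.

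The nuclear genome separated the livers most, with 2702 genes higher and 2803 lower in NZB than BL/6J. Cyp2c39, a cytochrome P450, was 0.787 ± 0.0857 and 0.548 ± 0.344 in BL/6J:C57 and BL/6J:NZB and 372 ± 11.2 and 592 ± 27.6 in NZB:NZB and NZB:C57 (log2 8.15, SE 0.09, adjusted p = 1.37e-16, limma). Elovl3, a fatty acid elongase, was 1324 ± 451 and 1715 ± 387 against 45.9 ± 14.8 and 66.1 ± 15.4, and the class I antigen gene H2-K1 was 1614 ± 137 and 1378 ± 88.3 against 130.5 ± 8.84 and 145 ± 4.995. Mup20 was 18254 ± 2666 and 14803 ± 2852 against 36.5 ± 9.12 and 535 ± 52.6. Akr1c18 and Mup2 rose by 6.00 and 5.94, while Mup7 and Wfdc21 fell by 6.59 and 6.98. Cyp3a41a and Eno1b had 0 reads in all 6 BL/6J livers, against 497 ± 76.0 and 116 ± 5.87 in NZB:NZB, but Cyp3a41a shares 99.9% of its words with other genes, foremost Cyp3a41b. Eno1b shares 88.4% of its words with other genes, Eno1 foremost, and the sum of Eno1b and Eno1 moved by -0.99 where Eno1b alone moved by 6.96. Cyp2c39, H2-K1 and the Mup genes also share sequence with other genes, so the levels of all these genes are uncertain. Mup19 was 12165 ± 3744 in BL/6J:C57 and 0 in all NZB:NZB livers.

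Cell cycle genes were higher in NZB livers, 34 of 35, and 34 adjusted over the list alone, with a median of 1.22 (adjusted p = 0.262 with an estimated correlation). Kif20a and Cdc20 rose by 2.47 and 2.42. Nuclear complex I genes were lower, 34 of 36, and 34 adjusted over the list alone, with a median of -0.46 (adjusted p = 0.441 with an estimated correlation). Antigen presentation genes had 16 of 26 down and 6 up, 17 and 6 adjusted over the list alone (adjusted p = 0.396 with an estimated correlation). Sarcomere genes, which a liver should hold only in traces, had 22 of 24 up, 22 up and 1 down adjusted over the list alone (adjusted p = 0.489 with an estimated correlation). Rps2, Ndufs5 and Pgk1 fell by 6.84, 5.73 and 3.10, and each shares sequence with a copy, so their own levels are uncertain. Without genes that share sequence, 4603 genes differed, and the label words mix and rep followed the nuclear genome throughout.

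In heart, 3681 genes were higher and 2545 lower with the NZB nuclear genome. Hamp2, a hepcidin gene, was 0.115 ± 0.10005 and 0.386 ± 0.437 in BL/6J:C57 and BL/6J:NZB and 22.2 ± 1.93 and 56.3 ± 6.79 in NZB:NZB and NZB:C57 (log2 4.90, SE 0.13, adjusted p = 7.37e-15, limma). The interferon-inducible gene Ifi202b rose by 4.36, AK157302 by 5.63, and Ogdhl, an oxoglutarate dehydrogenase-like enzyme, fell from 147 ± 14.7 and 143 ± 6.75 to 3.46 ± 0.492 and 6.30 ± 1.37. Eno1b and Scgb1a1 had 0 reads in all 6 BL/6J hearts, against 38.7 ± 5.04 and 50.1 ± 43.4 in NZB:NZB, while the sum of Eno1b and its copy Eno1 moved by -0.25. Rpl26, Rps2, Ndufs5 and Rpl29 fell by 6.97, 6.76, 6.20 and 5.26. These 4 genes, Eno1b and Hamp2 share sequence with copies, so their own levels are uncertain. Extracellular matrix genes had 32 of 33 up, 32 adjusted over the list alone, with a median of 1.17, and cell cycle genes 28 of 35, 28 adjusted over the list alone (adjusted p = 0.0635 for both with an estimated correlation). Complex I genes had 35 of 36 down, 36 adjusted over the list alone, with a median of -0.32, PPARA targets and fatty acid oxidation genes 29 of 35 down and 2 up, 29 and 3 adjusted over the list alone, and antigen presentation genes 17 of 25 down and 3 up, 17 and 3 adjusted over the list alone (adjusted p = 0.223, 0.142 and 0.203 with an estimated correlation). Without genes that share sequence 5476 genes differed, and library totals gave 2206 higher and 6649 lower with a median of -0.20.

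The change from BL/6J:C57 to BL/6J:NZB differed between heart and liver for 11 genes, 3 higher and 8 lower in heart minus liver. Another of 100 splits of these libraries called 565 genes, so the count of 11 is not attributed to the genotype. With the replicate number as a block the count was 3. Lbh, a transcription cofactor, went from 5.43 ± 1.04 to 9.05 ± 0.313 in liver and from 584 ± 48.1 to 474 ± 19.3 in heart (difference -0.95, SE 0.15, adjusted p = 0.0268, limma). The endothelin receptor Ednra, Ntn1 and Itga9 differed by -1.34, -1.18 and -1.21, and the M-band gene Myom3 by 1.38. At an unadjusted p under 0.05 there were 2502 genes, and edgeR called 47 and DESeq2 431. Leaving out liver BL/6J:C57 replicates 1, 2 and 3 gave 18, 3 and 1053, liver BL/6J:NZB replicates 5, 0 and 61, heart BL/6J:C57 replicates 0, 3 and 0, and heart BL/6J:NZB replicates 4, 0 and 2.

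The change from NZB:NZB to NZB:C57 differed between the tissues for 3571 genes, 2424 higher and 1147 lower in heart minus liver. Serpina6, which encodes corticosteroid-binding globulin, went from 239.8 ± 15.6 to 1561 ± 44.9 in liver and from 0.167 ± 0.00773 to 0 reads in heart (difference -2.92, SE 0.13, adjusted p = 3.60e-13, limma). Trim63, Asb10, Trim54 and Kcnj3 had 0 reads in NZB:C57 livers and at most a few in NZB:NZB livers, and the differences of 4.02, 3.75, 3.97 and 4.21 follow their heart values. Female-biased liver genes had 20 of 21 higher, 21 adjusted over the list alone, and male-biased genes 19 of 24 lower, 20 adjusted over the list alone (adjusted p = 0.000311 and 0.0367 with an estimated correlation). Library totals gave 1428 higher and 6562 lower with a median of -0.41, and DESeq2 and edgeR called 2137 and 2115.

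**Figure D3:**
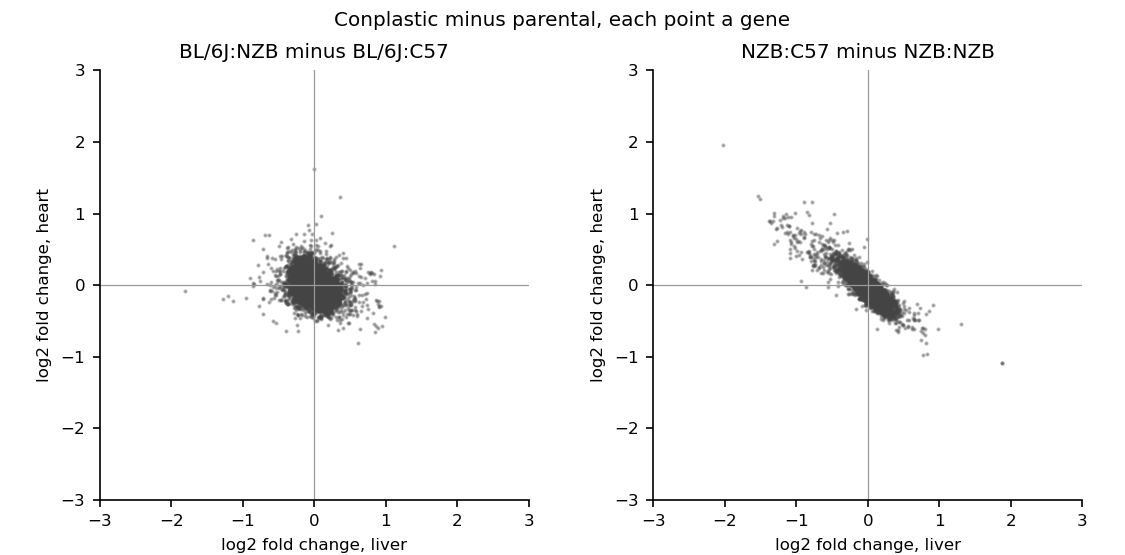
Log2 fold change of the conplastic against the parental line in liver (x axis) and heart (y axis), 1 point per gene, for the 7550 genes above 5 in every library, on the BL/6J nuclear genome (left) and the NZB nuclear genome (right). On the NZB nuclear genome the points lie along a falling line, with 81.0% of genes of opposite sign, against 61.3% on BL/6J.

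Of the single genes fixed in advance, Nnt, the mitochondrial transhydrogenase that lacks exons in some C57BL/6J stocks, was read in every library. In liver it was 146 ± 5.59 in BL/6J:C57, 157 ± 2.85 in BL/6J:NZB, 195 ± 6.80 in NZB:NZB and 159 ± 2.52 in NZB:C57, and in heart 993 ± 80.7, 884 ± 36.0, 788 ± 22.6 and 933 ± 28.1. From NZB:NZB to NZB:C57, Nnt changed by -0.29 in liver (adjusted p = 0.0196, limma) and by 0.24 in heart (0.0239), a direction that library totals turned to -0.46. Cox7a2l, which takes part in respiratory supercomplexes and differs in length between mouse strains, changed by 0.02 and 0.07 in liver and 0.11 and -0.10 in heart on the BL/6J and NZB nuclear genomes, none past the threshold. In liver these directions turned without BL/6J:C57 replicate 2 (-0.0091) on BL/6J and with library totals (-0.17) on NZB. Across nuclear genomes Cox7a2l differed by -0.24 in liver and -0.37 in heart (adjusted p = 0.00233 and 2.90e-05). It shares 21.1% of its words with other genes, foremost Gm6969, which differed by 3.87 and 4.73. The sum of Cox7a2l and Gm6969 moved by 0.05 and -0.08, so the level of Cox7a2l itself is uncertain. Mmrn1 had 0 reads in all 12 BL/6J-nuclear libraries. In NZB:NZB and NZB:C57 hearts it was 4.89 ± 0.193 and 10.7 ± 2.04.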

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

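All tests in this part were chosen after the result they bear on was seen, except the tests of tissue differences and the sum of gene and copy over all 39 genes.

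The effects of mtDNA were tested for a difference between tissues, which gave 11 genes on the BL/6J nuclear genome and 3571 on the NZB nuclear genome. The smallest p-values on BL/6J belonged to Lbh (-0.95), Ednra (-1.34), Ntn1 (-1.18), Itga9 (-1.21) and Myom3 (1.38), as heart minus liver on the log2 scale. Those on NZB belonged to Trim63 (4.02), Asb10 (3.75), Trim54 (3.97), Serpina6 (-2.92) and Kcnj3 (4.21). On NZB, all 5 genes had 0 reads in the 3 NZB:C57 libraries of the tissue where they are low, so the part from that tissue depends on the pseudocount. Most of each difference comes from the other tissue, such as Trim63 from 93.4 to 1221 in heart and Serpina6 from 239.8 to 1561 in liver.

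Changes of liver and heart on the NZB nuclear genome mirrored each other gene by gene: over 7550 genes above 5 in every library, Pearson's r across genes was -0.87 and Spearman's rho -0.84, and genes are not independent replicates. The mean of both effects varied less than replicate noise allows, with a ratio of variances of 0.343 against a lowest value of 0.698 in the other 199 of 200 relabellings of the NZB libraries, which argues against opposite responses of independently processed tissues. With 100% of values at whole reads, an adjustment of normalised values is also argued against, but not one that returns whole counts. What stays open is that the read counts of NZB-nuclear libraries may have been adjusted across both tissues before deposit, the hypothesis that the ratio of 0.343 fits. On the BL/6J nuclear genome the ratio was 1.19 and relabelling alone reached 0.524, so low ratios can arise from the structure of the libraries.

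Of 351 heart-enriched transcripts (at least 20 times the level of BL/6J livers), 138 had more NZB:C57 than NZB:NZB livers at 0 reads and rose in NZB:C57 hearts by a median of 2.12, against 0.56 for 208 with equal numbers, a gap of 1.56. Livers at 0 reads follow the liver change, which mirrored that of hearts over the 7550 genes above 5 in every library. Genes with a library at 0 reads lie outside that set. Both kinds of transcript also differ in level (medians of 70.4 and 153 in BL/6J hearts). An adjustment set by libraries of the other tissue without reads therefore cannot be told apart from the mirroring itself. A larger share of cardiomyocytes as the only cause would raise their markers alike, and is argued against by an interquartile range of 1.49 over 13 markers (1.64 to 3.13), beside a median SE of 0.10, with Csrp3 at -0.07. A larger share together with other changes stays open. Liver changes went with hearts at 0 reads likewise (medians of 0.01, 1.29 and 2.24 at 0, 1 and 2 more NZB:C57 hearts), and a direct response of heart muscle to C57 mtDNA was not tested beyond this.

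Of 48 genes at least 3 log2 units apart between nuclear genomes in both tissues, 40 (83.3%) share at least 10% of their words with another gene, against 14.1% of all genes. Where the copy is in the table (39 genes), the sum of gene and copy moved by a median of 0.0873 of the gene's own change, and by 0.0873 in the 27 genes at least 0.5 times as abundant as their copy. Rpl29 fell by 5.19 in liver while Gm13841, its copy, rose by 7.33, with a sum that moved by 0.00, and 31 of the 39 ratios were under 0.5. A small ratio alone does not show that reads were shared out differently, because the genes were chosen for large changes of their own. Stmn1, the copy of Gm11223, hardly moved (0.08 in liver, 0.02 in heart), yet the ratio was 0.339. Other copies moved the opposite way, such as Rpl26 (-6.24 in liver) and Gm15772 (7.69), and both members of such pairs are among the 39. Only for such pairs do the values go with reads shared out differently among copies. Whether variants of the NZB strain or other processing of its libraries moved the reads cannot be told apart, since all 12 libraries of each nuclear genome carry 1 label word.

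Other splits of the same libraries were counted for each comparison. For a conplastic line against its parental line there are 10 splits, too few for a share under 0.05. The real and the highest other counts were 1 and 3 for BL/6J liver (4 splits with as many genes, the real one included), 129 and 0 for BL/6J heart (1 split), 1064 and 0 for NZB liver (1 split), and 2190 and 2 for NZB heart (1 split). For the other comparisons 100 splits were counted, the real one and others drawn at random. A highest other count therefore covers the drawn splits only. Among them, chance could not be excluded for mismatch in liver, where 7 splits gave as many genes (328, highest other 659). The split by mtDNA calls 876 genes there and was not drawn. For mismatch in heart (1550) 2 splits gave as many, the real one and, at 1945, the split by mtDNA. Both keep the difference between NZB:C57 and NZB:NZB hearts, which alone called 2190 genes against 129 on BL/6J. The low share therefore does not single out mismatch. Only the real split gave as many for mtDNA in liver (876, highest other drawn 579) and heart (1945, highest other drawn 1347). The split by mismatch calls 1550 genes in heart and was not drawn there. Only the real split did so as well for the nuclear genome in liver (5505, highest other 653) and heart (6226, highest other 2900), and for the tissue difference on NZB (3571, highest other 1377). These shares take the libraries as exchangeable, which counts adjusted across libraries before deposit would not be. For the tissue difference on BL/6J (11 genes), 3 of 100 splits, the real one included, gave as many, a share under 0.05, but the highest other split gave 565. That points to a structure of the samples other than the genotype, so the count of 11 is not attributed to the genotype here.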

How the results depend on the processing

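The tests with edgeR, with recomputed TMM factors, over genes with reads in every NZB-nuclear library and without genes sharing sequence were chosen after seeing the data. Each of 178 changes of a named gene in a comparison was recomputed under each alternative that covers its comparison and tests the gene, which were 170 with DESeq2, 97 with only the 6 libraries compared, 51 over genes with reads in every NZB-nuclear library and 9 without genes sharing sequence. Of 3305 values, 3029 kept their direction and side of the threshold, 272 lost the call, of which 178 by leaving out 1 library, 1 gained it and 3 reversed, and 128 of the changes kept both wherever they were tested. The reversed values were Cox7a2l in BL/6J livers without BL/6J:C57 replicate 2 (-0.0091, with up to 0.064 when other libraries are left out), Cox7a2l in NZB livers with library totals (-0.17) and Nnt in NZB hearts with library totals (-0.46). The causes below were not tested unless stated. Depth limits low genes: 1 read is worth up to 0.221 in a heart library and 0.194 in a liver library.

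The count for BL/6J livers (1) was 0 without a low-value filter (a filter tests fewer genes), 0 with only the 6 libraries compared (fewer samples), 2 at a pseudocount of 0.5, 3 with edgeR and 84 with DESeq2. That for BL/6J hearts (129) was 3 without the filter, 1 with the 6 libraries, 322 with edgeR and 423 with DESeq2. The tissue difference on BL/6J (11) was 20 with RLE factors, 56 with library totals, 5 at a pseudocount of 0.5, 47 with edgeR and 431 with DESeq2, and that on NZB (3571) was 2137 with DESeq2 and 2115 with edgeR. Library totals gave 2917 for NZB liver, 2963 for mtDNA in liver, 11036 for NZB heart, 9127 for mismatch and 9870 for mtDNA in heart, and 7990 for the tissue difference on NZB. The medians of all genes shifted with the totals, to -0.65 in NZB heart. Genes with reads in every NZB-nuclear library numbered 598, 46 and 541 for NZB, mismatch and mtDNA in liver, 1054, 592 and 1033 in heart, and 1995 for the tissue difference on NZB (fewer genes tested).

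A pairing by replicate number was not shown: in 0 of 8 sets did every pair of same-numbered libraries correlate above 0.1, and correlations ran from -0.16 to 0.25. A weak pairing of liver with heart is not excluded by this rule. For BL/6J:C57, BL/6J:NZB, NZB:C57 and NZB:NZB, same-numbered liver and heart libraries had mean correlations of 0.017, 0.103, 0.079 and 0.024. Those with other numbers had -0.008, -0.050, -0.039 and -0.012. With the number as a replicate block, BL/6J livers had 7 genes, BL/6J hearts 66 and the tissue difference on BL/6J 3, and every other count stayed within 1.5 times its value.

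Leaving out each library gave ranges of 1 to 195 (BL/6J), 681 to 923 (NZB), 259 to 482 (mismatch), 611 to 1370 (mtDNA) and 4893 to 6101 (nuclear genome) genes in liver. In heart they were 6 to 193, 1809 to 2022, 1315 to 1687, 1600 to 1943 and 5711 to 6247, and for tissue differences 0 to 1053 (BL/6J) and 3095 to 3370 (NZB). The libraries behind changes over 1.5 times stand with each comparison in the report.

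Lists past the threshold with camera, in the order above, numbered 15, 12, 18, 13 and 22 in liver, 17, 18, 18, 22 and 26 in heart, and 23 and 19 for the tissue differences. With an estimated correlation these became 0, 3, 2, 2 and 0 in liver, 0, 7, 6, 6 and 0 in heart, and 0 and 3. With fry, which does not compare a list with other genes, they were 1, 9, 6, 11 and 27 in liver. In heart fry gave 1, 19, 13, 20 and 35, and for the tissue differences 0 and 22. Leaving out libraries gave 11 to 17, 11 to 17, 10 to 20, 14 to 18 and 21 to 25 in liver, 14 to 20, 16 to 20, 14 to 20, 20 to 24 and 25 to 27 in heart, and 18 to 22 and 18 to 21. Mismatch in liver had 10 lists without BL/6J:C57 replicate 1.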

Other observations

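No test in this part was planned as a hypothesis, and the values below were chosen after they were seen, except the gene lists.

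Members of other gene groups differed between nuclear genomes. In liver, cholesterol synthesis genes had 13 of 25 members higher and 1 lower with the NZB nuclear genome, 13 and 1 adjusted over the list alone (limma camera adjusted p = 0.00265, adjusted p = 0.489 with an estimated correlation). Autophagy and lysosome genes had 19 of 36 lower and 4 higher, 20 and 4 adjusted over the list alone, and immediate early genes 10 of 20 lower, 10 adjusted over the list alone (adjusted p = 0.372 and 0.489 with an estimated correlation). Of the interferon-stimulated genes, 17 of 38 were lower and 2 higher in liver, 17 and 4 adjusted over the list alone, and 21 of 37 lower and 1 higher in heart, 22 and 1 adjusted over the list alone (adjusted p = 0.489 and 0.204 with an estimated correlation). In NZB hearts, complex II and III genes had 11 of 13 lower, complex IV genes 10 of 14 lower and 2 higher, and ATP synthase genes 14 of 15 lower and 1 higher, and adjusted over the list alone 13 lower, 10 lower and 2 higher, and 14 lower and 1 higher (adjusted p = 0.249, 0.461 and 0.335 with an estimated correlation). ER chaperone genes had 13 of 20 higher and 2 lower in liver, 15 and 2 adjusted over the list alone, and 16 of 20 higher in heart, 16 adjusted over the list alone (adjusted p = 0.556 and 0.461 with an estimated correlation).

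Transcripts of heart muscle were read in livers with the NZB nuclear genome. Myh6 had 463, 243 and 119 reads in the NZB:NZB livers and 0, 240 and 214 in the NZB:C57 livers, while the 6 BL/6J livers held 0 or 1 read each. In hearts, Myh6 had between 50718 and 1089168 reads.

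Gm13340 had 6, 13 and 11 reads in BL/6J:C57 livers and 270, 108 and 117 in BL/6J:NZB livers. Hearts held 12, 9 and 8 against 678, 691 and 920. On the NZB nuclear genome it was 17.2 ± 1.23 with NZB mtDNA and 11.7 ± 4.49 with C57 mtDNA in liver, and 36.4 ± 2.97 and 23.3 ± 4.64 in heart. In both tissues it was thus lower with the C57 mtDNA label, as on the BL/6J nuclear genome, with no overlap between libraries. In liver the margin was small, with a highest NZB:C57 value of 15.6 and a lowest NZB:NZB value of 15.8. NZB:C57 still lay nearer to NZB:NZB than to BL/6J:C57 in both tissues, although NZB:C57 and BL/6J:C57 carry the same mtDNA label. Since Gm13340 is annotated as a pseudogene of chromosome 2 and its reads cannot be assigned with certainty, it does not settle whether the mtDNA labels of NZB-nuclear libraries hold.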
